A study of Mus musculus with 10 samples.

How the data were processed

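Messenger and other long RNA was measured in 10 retinas of wild-type C57BL/6J mice on postnatal day 34, the left and the right retina of 5 mice numbered 61, 64, 65, 66 and 68. Per the labels' protocols, a lens of −20 dioptres (which moves the focal plane behind the retina and makes the growing eye myopic) was worn in front of one eye of each mouse for 10 days from postnatal day 24. The fellow eye was left untreated. Libraries were made from total RNA with a strand-specific kit after removal of ribosomal RNA. The labels give the side of each retina and the number of the mouse but not which eye wore the lens. The groups are therefore left retina and right retina, with 5 libraries each, and no library is called lens-treated or control.

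The deposited values are CPM (counts scaled to a common library size), not divided by gene length, and 0.0001 was added to every value. This unit was read from the values, since the sources used here do not state it: once the 0.0001 is taken off, most low values of a library are multiples of a single step. Alignment with STAR and processing with Partek on mouse genome GRCm38 (mm10) are named in the submitters' processing notes. Versions, the counting rule and any filter on genes are not given in the sources used here. The labels also say that the raw files of the right retina of mouse 64 hold unequal numbers of forward and reverse reads because of a damaged file. The table holds 25905 genes, of which 16635 are protein-coding and 3691 are long noncoding RNA genes. Coordinates below are those deposited on GRCm38, with the end set 1 base before the deposited stop, because 25107 of the 25272 genes whose symbol is in GENCODE M21 end there in that annotation.

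The step gives the depth. One count was worth 0.00879 to 0.0112 CPM, so that the CPM of a library were taken over 89600000 to 113800000 counts and 1 CPM stood for 89.6 to 113.8 counts. The step was searched within a preset narrow range. The listed genes summed to 321661 to 346696 CPM, or 29680000 to 37250000 counts, and the rest of the denominator is not in the listed genes. Of the values up to 20 times the step, 90.6% to 91.6% were whole multiples within a tolerance of 0.1, too few to take the values as whole reads, so the edgeR test planned for counts was not run.

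Values were analysed as log2(CPM + 1), a scale on which the change of weakly expressed genes is understated. The 14210 genes with a mean of at least 1 CPM over the 10 libraries were tested. Right minus left was fitted with limma 3.58.1 (R 4.3.3) with the mouse as a block and moderated variances that follow the expression trend. The test was two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The 2 retinas of a number come from the same animal. Their deviations from the means of their sides correlated across genes at 0.607, 0.143, 0.166, 0.172 and 0.311 in mice 61, 64, 65, 66 and 68, and 5 of the 10 libraries correlated best with the fellow eye among the libraries of the other side. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 in the same fit, over the 37 of 42 lists that had at least 5 tested members. Because the lens side is unknown, a second test asked which genes differed between fellow eyes whichever the side. The mean square of the 5 right-minus-left differences, without removing a side effect, was compared with the trend of all genes by an F distribution whose prior was fitted by limma, one-sided. Genes differing between mice were tested with limma's moderated F-test over the mouse terms. The share of the sum of squares taken by mouse and by side was computed per gene, and the right-minus-left profiles were correlated between mice across genes, which are not independent replicates.

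The gene lists, the tests and the rule for naming genes were fixed before the data were examined. By that rule the text names the 12 genes per direction with the largest difference among genes that pass right against left and go the same way in 5 of 5 mice, filled up to 10 by lowest unadjusted p where fewer pass; the 3 members with the lowest p of each list that passes or holds a member passing over the list alone; the 10 genes farthest above the trend in the between-eye test; the 10 genes with the widest range among those differing between mice, sex-linked genes apart; and 16 genes named whatever their result, which include the immediate early genes Egr1 and Fos, the amacrine peptides Vip and Penk, and the opsins. Predicted genes without a name were passed over. A few genes counted in the totals are not reported here by name.

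The tests were tried on simulated data with the real means of 14210 genes, a small set of them changed. The simulation was first run with the variances as fitted, under which the between-eye test called none of its changed genes, and was then run with the moderated variances as well, a step taken after that outcome was seen. Of genes changed by 0.25, 0.5 and 1 log2 units between the sides, 44.8%, 98.5% and 100% were called with moderated variances (11 false calls), and 37.3%, 82.1% and 97% with variances as fitted (8 false calls). Of genes whose between-eye standard deviation was enlarged 3 and 6 times, 9% and 74% were called with moderated variances (32 false calls). With variances as fitted 0% of both were called (0 false calls). The power and the false calls of this test thus depend on how gene variances are spread. Of genes shifted by 0.25, 0.5 and 1 log2 units between mice, 3%, 56.7% and 100% were called with moderated variances (14 false calls), and 0%, 26.9% and 80.3% with variances as fitted (5 false calls). Of 5 gene lists shifted, the 1 at 0.05, the 2 at 0.1 and the 2 at 0.2 log2 units were called, and 0 of 29 unshifted lists that share no gene with them, with either kind of variance. The simulated errors were drawn independently for each gene. The false calls above therefore do not show how the tests, camera above all, behave where genes move together.

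Alternatives covered the pseudocount, the filter, quantile normalization and median centring, each mouse left out in turn, the variance model, library weights, the block, the set test and the lists. The plan named a robust prior for the between-eye test without saying which kind; a prior with its own degrees of freedom per gene was run first and a shared one after, and both are reported. Added after seeing the data were limma-voom on the counts implied by the step, a fit without mice 65 and 68, and a correction of each library for gene length and GC content, which 14032 of the tested genes (98.7%) had in GENCODE M21. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.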

Results

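Total RNA of 10 mouse retinas, 5 left and 5 right, was sequenced after 10 days in which 1 eye of each mouse looked through a −20 dioptre lens. The study asks how retinal transcripts respond when the eye is driven towards myopia. As the labels name the side of each retina and not its lens, the comparisons open to these data are right against left, fellow eye against fellow eye whichever the side, and mouse against mouse. By the step inferred from its values, each library held 29680000 to 37250000 counts in listed genes, and 1 CPM rested on 89.6 to 113.8 counts.

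No gene passed the test of right against left over all genes. Transcripts of the cone opsins differed by less than the spread between replicates. Opn1sw, the short-wave opsin, stood at 96.2 ± 18.5 CPM on the left and 96.3 ± 10.9 CPM on the right (SD, n = 5 each), with a difference of 0.01 log2 units (95% interval −0.14 to 0.16), and Opn1mw, the middle-wave opsin, at 27.1 ± 3.26 and 26.4 ± 2.45 CPM. Of genes long tied to visually guided eye growth, Egr1, an immediate early transcription factor, and Vip, a peptide of amacrine cells, were lower on the right in 5 of 5 mice. Vip (chromosome 10, bases 5639218 to 5647617 of GRCm38) measured 2.97 ± 0.447 CPM on the left and 1.97 ± 0.34 CPM on the right, a difference of −0.42 log2 units (SE 0.08, 95% interval −0.60 to −0.24). Egr1 (chromosome 18, bases 34859823 to 34864984) measured 8.68 ± 13.3 and 6.67 ± 10.8 CPM, with the spread set by mouse 61, and within mice the difference was −0.38 (SE 0.09, 95% interval −0.58 to −0.18). The size depends on the pseudocount: with 0.1 and 5 CPM in place of 1 CPM it was −0.57 and −0.19 for Vip and −0.51 and −0.20 for Egr1, and limma-voom gave −0.58 and −0.43. Over all 14210 genes neither passed (limma adjusted p = 0.9996), and both passed when adjusted over the list alone of the 13 tested genes that were to be named whatever their result (adjusted p = 0.0056 and 0.0112). The call of Egr1 over that list was lost where the mouse was not a block, which left 1 gene, Vip, and without mouse 64 the list had 4 such genes, with Cryaa and Rpe65 added.

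Among the other genes on that list, Fos was lower on the right in 4 of 5 mice (−0.16, SE 0.07), and Penk, the enkephalin precursor (chromosome 4, bases 4133531 to 4138819), was higher on the right in 3 mice and lower in 2 (0.37, SE 0.31). Aplp2, Gjd2, Gfap, Aldh1a1, Opn1mw and Rpe65 differed by −0.01, −0.02, −0.03, 0.17, −0.03 and 0.21 log2 units, each with an interval that spans 0. Cryaa is described with the lens genes. Th, the rate-limiting enzyme of dopamine synthesis, Opn4, the melanopsin of intrinsically photosensitive ganglion cells, and Bmp2 lay under the filter, at 0.835, 0.625 and 0.313 CPM on the left and 0.651, 0.548 and 0.383 CPM on the right.

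Limma called 0 of 14210 genes between the sides. At an unadjusted p under 0.05 limma had 333 (218 higher and 115 lower on the right), where chance gives 710. Genes move together, so that count can stray far from 710. Over the 16 groupings of the libraries that part all pairs of fellow eyes, it ran from 136 to 3836. A count below 710 thus does not show that the sides are alike. Limma-voom on the implied counts also called 0, with 336 at an unadjusted p under 0.05, and limma without the mouse as a block 0, with 188. By signs alone, 395 genes were higher and 286 lower on the right in all 5 mice, 4.79% of genes where chance gives 6.25%. The genes of lowest p that went 1 way in 5 of 5 mice are given as values, and none passed. Higher on the right were Zfp433 (0.30, SE 0.06), the collagens Col1a2 (0.40, SE 0.09) and Col8a1 (0.30, SE 0.09), Wdr31 (0.19), Pcbp1 (0.22), Arhgef5 (0.30), Dut (0.23), Igfbp4 (0.22), Olfml3 (0.32) and Maf (0.29). Lower on the right, beside Vip and Egr1, were Fcamr (−0.44, SE 0.09), Rsc1a1 (−0.32, SE 0.07), Dio2, which encodes the deiodinase that activates thyroid hormone (−0.32, SE 0.08), Rdh8, a photoreceptor retinol dehydrogenase (−0.13), Rps21 (−0.28), Nab2, a corepressor of Egr1 (−0.26, SE 0.08), Mapk11 (−0.20) and Traip (−0.20). With 5 pairs an exact sign-flip test of a single gene cannot give a two-sided p below 0.0625.

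**Figure D1:**
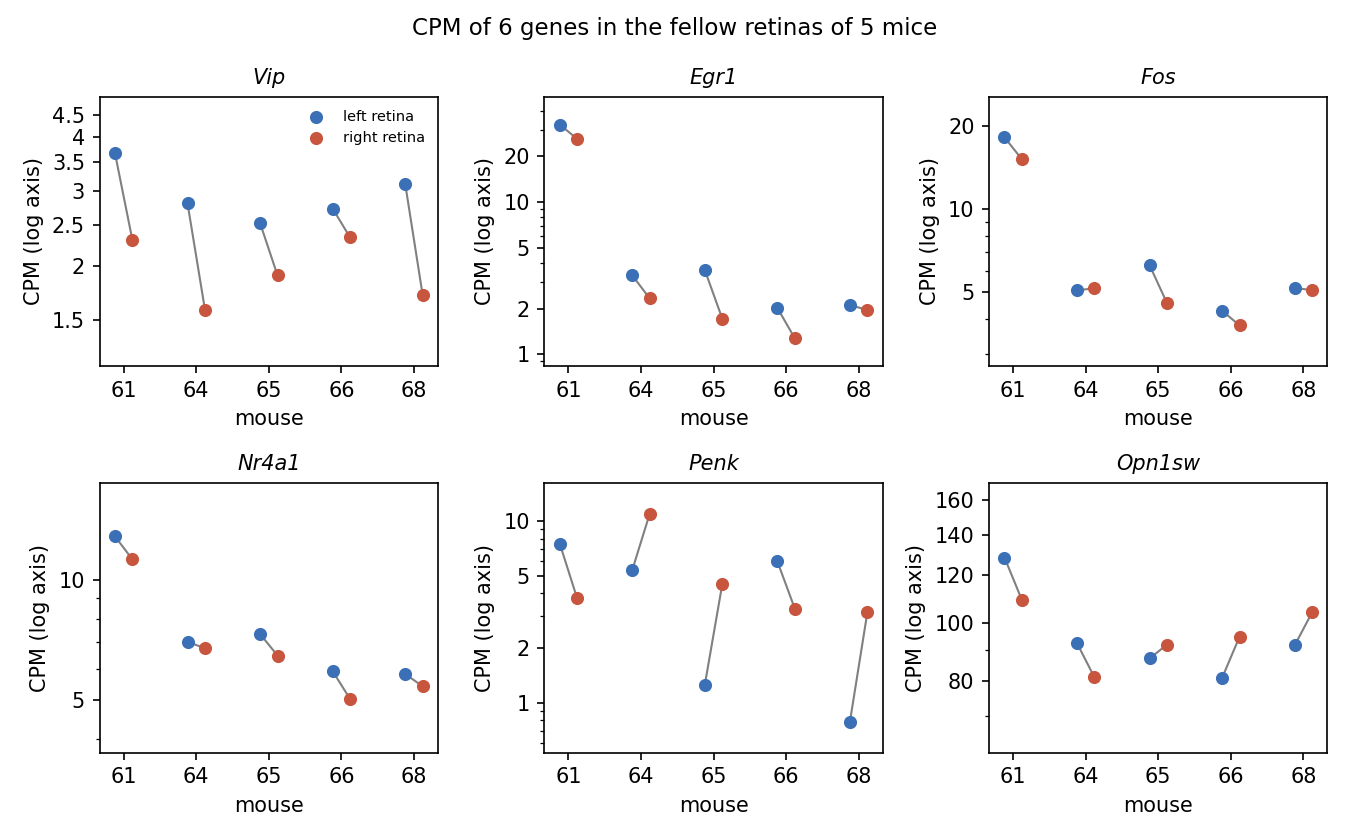
CPM on a log axis of 6 genes in the left (blue) and right (red) retina of each of 5 mice, with a line joining fellow eyes. Vip and Egr1 were lower on the right in 5 of 5 mice, Penk went both ways, and Egr1, Fos and Nr4a1 stood highest in both eyes of mouse 61.

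Gene lists fixed beforehand gave a second reading of right against left. Of 37 lists, 12 passed camera, 8 higher and 4 lower on the right, and none passed with an estimated correlation (smallest adjusted p = 0.43 with an estimated correlation) or with fry. The largest shift was that of lens genes: 16 of 17 tested members were higher on the right, by 1.08 log2 units on average (adjusted p = 1.96e-14, and adjusted p = 0.43 with an estimated correlation). Among them were the lens filament gene Bfsp1 (0.62, SE 0.18) and the crystallins Crygb (0.83, SE 0.32) and Crygs (1.49, SE 0.58). Members of the matrix list were higher in 28 of 36 cases (mean 0.20, adjusted p = 1.85e-09, and 0.43 with an estimated correlation), with Col1a2, Col8a1 and Fmod (0.52, SE 0.17) at its head. Fibroblast genes of sclera and connective tissue were higher in 10 of 11 (mean 0.29, adjusted p = 1.57e-07, and 0.43 with an estimated correlation), and Col1a2, but not Col1a1 (0.31, SE 0.13), passed adjusted over the list alone. Pigment epithelium genes were higher in 11 of 13 (mean 0.14, adjusted p = 0.00155, and 0.611 with an estimated correlation), led by Enpp2 (0.17), Trpm3 (0.09) and Pmel (0.27). The lens mean differed by 3.71 in mouse 65, 1.19 in mouse 66, 0.76 in mouse 68 and 0.30 in mouse 61, against −0.56 in mouse 64. The pigment epithelium mean differed by 0.46, 0.23, 0.32 and 0.06 in the same mice, against −0.36 in mouse 64, and the fibroblast mean by 0.63 in mouse 65 and 0.64 in mouse 68, against 0.02 to 0.08 in the other mice. The skeletal muscle list was lower on the right in 8 of 8 members (mean −0.47, adjusted p = 0.000271, and 0.609 with an estimated correlation). It lay between −0.08 and 0.11 in 4 mice and at −2.33 in mouse 68. There the left retina held Myh4 at 21.8 CPM, Atp2a1 at 13.6 CPM and Acta1 at 10.0 CPM. In the other left retinas these genes were at most 0.65 CPM, and their means on the right were at most 0.534 CPM. They thus reached the filter of a mean of 1 CPM only through the left retina of mouse 68. Genes let in this way must be lower on the right on average, so the 8 of 8 and its p were partly built in.

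Müller glia genes were higher in 17 of 20 (mean 0.04, adjusted p = 0.0118, and 0.645 with an estimated correlation), with Aqp4, a water channel (0.07), Kcnj10 (0.13) and Clu (0.12) in front, and reactive glia genes in 12 of 13 (mean 0.07, adjusted p = 0.00605, and 0.43 with an estimated correlation), with Fgf2 (0.11), Mt2 (0.17) and A2m (0.12). TGF-beta and BMP genes were higher in 21 of 28 (mean 0.04, adjusted p = 0.0256, and 0.609 with an estimated correlation), led by Tgfbr3 (0.23), Bmpr1b (0.16) and Inhba (0.16). All 13 mitochondrially encoded genes were higher on the right on average (mean 0.10, adjusted p = 0.0066, and 0.645 with an estimated correlation), mt-Nd4l (0.24), mt-Co3 (0.06) and mt-Co2 (0.10) among them, but the list was higher on the right in mice 61, 64 and 68 (0.19, 0.56 and 0.18) and lower in mice 65 and 66 (−0.20 and −0.23). Immediate early genes were lower in 14 of 18 (mean −0.06, adjusted p = 0.00605, and 0.43 with an estimated correlation). Nr4a1, an orphan nuclear receptor induced by activity, was lower in 5 of 5 mice (−0.13, SE 0.05), and Egr1 passed adjusted over the list alone. Heat shock and unfolded protein genes were lower in 13 of 20 (mean −0.03, adjusted p = 0.0126, and 0.43 with an estimated correlation), with the stress transcription factors Atf4 (−0.10), Ddit3 (−0.13) and Atf3 (−0.14) each lower in 5 of 5 mice. Synaptic vesicle genes were lower in 23 of 29 (mean −0.02, adjusted p = 0.0348, and 0.609 with an estimated correlation), with Cplx2 (−0.09), Cplx3 (−0.06) and Rims2 (−0.05).

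Without mice 65 and 68, a fit added after seeing the data, 3 of the 12 lists still passed, namely lens (adjusted p = 3.93e-06), mitochondrially encoded (7.43e-05) and immediate early genes (0.0047), with an adjusted p of 0.43, 0.645 and 0.43 with an estimated correlation in the fit of all 5 mice. Among mice 61, 64 and 66 the lens list (0.30, −0.56 and 1.19) and the mitochondrially encoded list (0.19, 0.56 and −0.23) went both ways. The means of the lens, matrix and fibroblast lists were then 0.31, 0.02 and 0.06, and those of the pigment epithelium, Müller glia and muscle lists −0.02, −0.01 and −0.01. Those of the reactive glia and TGF-beta lists were 0.024 and 0.007. The mitochondrially encoded, immediate early, heat shock and synaptic lists had means of 0.171, −0.084, −0.018 and −0.03. Without mouse 65 alone or mouse 68 alone, 5 lists passed. Of the 5 fits that leave out a mouse, the lens, matrix and fibroblast lists passed in 5, Müller glia in 4, reactive glia, pigment epithelium and TGF-beta in 3, the mitochondrially encoded, immediate early and heat shock lists in 2 and the synaptic list in 1. The muscle list passed in 4 and without mouse 68 had under 5 tested members. Where the mouse was not a block, the immediate early, heat shock and synaptic lists did not pass (adjusted p = 0.255, 0.0822 and 0.0586). The mitochondrially encoded list was lower on the right without mouse 64 (adjusted p = 0.591).

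The other 25 lists did not pass in the fit of all 5 mice. Rod phototransduction was nearest to the threshold, with 17 of 26 members lower on the right (mean −0.02, adjusted p = 0.072), followed by bipolar cells and by genes at human refractive error loci (means −0.02 and 0.03, adjusted p = 0.12 for both). Cones, horizontal cells, ganglion cells, dopamine signalling, the circadian clock, retinoid metabolism, WNT signalling, glutamate receptors, GABA and glycine receptors, microRNA machinery and genes of high-grade human myopia had means from −0.02 to 0.04 and adjusted p from 0.353 to 0.992. Vascular cells, nuclear genes of oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins, hypoxia, interferon, complement, cholesterol synthesis, insulin signalling, and iris and ciliary body had means from −0.02 to 0.06 and adjusted p from 0.234 to 0.863. Several of these lists passed camera when a mouse was left out. Without mouse 64 the glycolysis (adjusted p = 0.00768) and ribosomal lists (0.045) passed as higher on the right, and the bipolar (0.0407) and ganglion cell lists (0.045) as lower. Without mouse 66 the refractive error list (0.0432) passed as higher, and the rod (0.0128), cone (0.0278) and nuclear oxidative phosphorylation lists (0.0465) as lower. Without mouse 61 the iris and ciliary body list passed as higher (0.00531). The rod list also passed as lower after correction for length and GC content (0.0287), and the complement (0.00284) and iris lists (0.0267) as higher with no filter. Estimated correlations were not fitted in these settings. The retinoid and ribosomal lists had a mean above 0 and a camera direction below it. Microglia, cornea, oligodendrocyte and blood lists had fewer than 5 tested members and were not tested. In the amacrine list (adjusted p = 0.79) Vip passed adjusted over the list alone, Dab1 was higher (0.12, SE 0.05) and Calb2 lower (−0.11, SE 0.07) on the right.

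**Figure D2:**
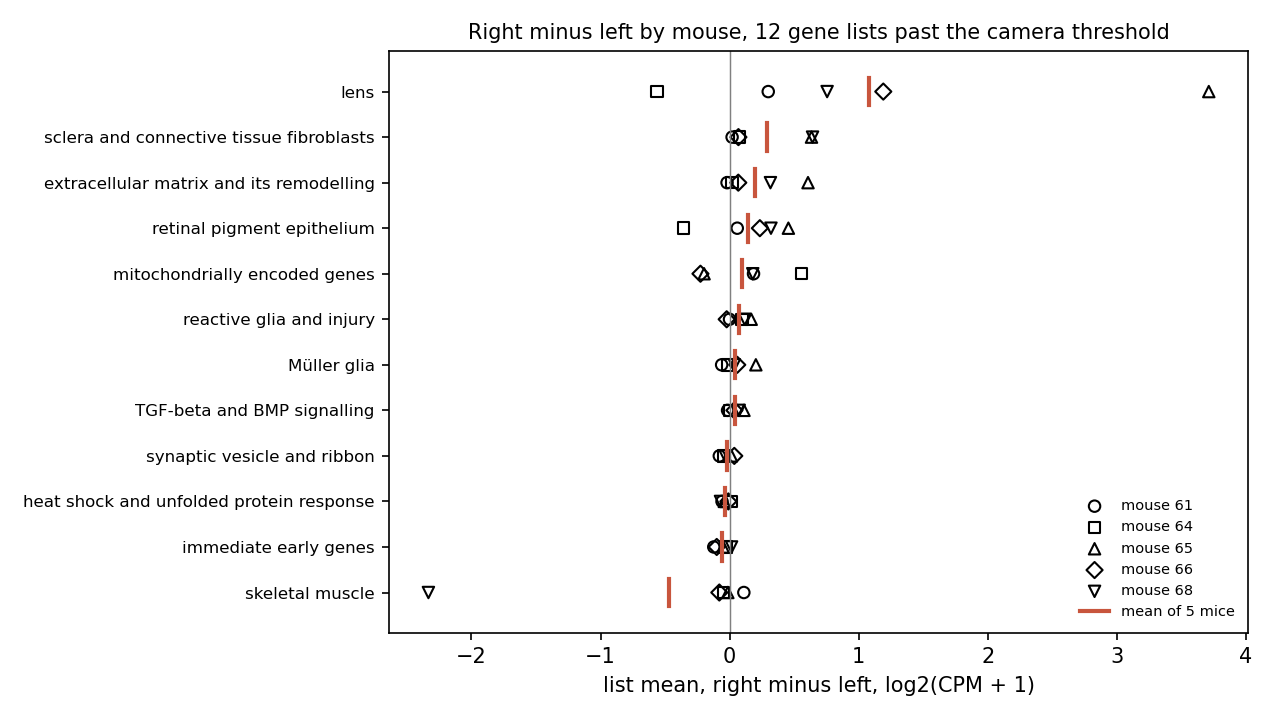
Mean right-minus-left difference in log2(CPM + 1) of the 12 gene lists that passed camera, with a symbol for each of 5 mice and a red bar for their mean. The lens list reaches 3.71 in mouse 65 and the skeletal muscle list −2.33 in mouse 68, and the mitochondrially encoded list 0.56 in mouse 64.

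Because 1 eye of every mouse wore the lens, the fellow eyes were also compared without regard to side. In this test 48 genes differed between fellow eyes more than genes of like level, with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 669, where chance gives 710. The trend and its spread were fitted to these same genes, so a count near that number was largely built in. It does not show whether fellow eyes differed broadly. In the simulation with moderated variances this test made 32 false calls, more than its threshold allows, so the 48 may hold false calls above that rate. Of the 48, 14 were lens genes, 6 were skeletal muscle genes and 28 were neither. Among the 10 genes farthest above the trend were 7 crystallin genes (Cryaa, Cryba1, Crybb2, Cryab, Crygs, Cryba2 and Crybb3), the giant muscle protein gene Ttn and Optc, which encodes a proteoglycan of the vitreous. Cryaa (chromosome 17, bases 31677807 to 31681733) was at 387 CPM in the right retina of mouse 65 and at 2.33 to 42.0 CPM in the other 9, a between-eye difference of 6.86 log2 units in mouse 65 (adjusted p = 6.43e-05 in the between-eye test). Ttn (chromosome 2, bases 76703980 to 76982547) was at 189.6 CPM in the left retina of mouse 68 and at 24.9 to 30.1 CPM in the others. Crygb, Crygc and Crygd are close relatives in sequence, and the way reads were shared among them is not known.

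Optc and Penk had the same sign in each of the 5 mice. Optc (chromosome 1, bases 133897199 to 133907999) was higher on the right by 2.90 in mouse 65, 2.56 in mouse 68 and 0.35 in mouse 64, and lower by 0.68 and 0.67 in mice 61 and 66. Penk, in the same order of mice, had differences of 1.28, 1.21 and 0.91 against −0.84 and −0.70 (adjusted p = 0.0021 and 0.035 in the between-eye test). The right-left difference was greatest in mouse 65 for 30 of the 48 genes and in mouse 68 for 7. Without mice 65 and 68, 4 genes passed, all 4 of them among the 48, and without mouse 65 or mouse 68 alone 30 and 23 passed. With a robust prior the count was 109, or 0 where each gene had its own prior degrees of freedom. That last version gives outlying genes fewer prior degrees of freedom, and it left 3 genes at an unadjusted p under 0.05. Its 0 was therefore largely set by the method.

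**Figure D3:**
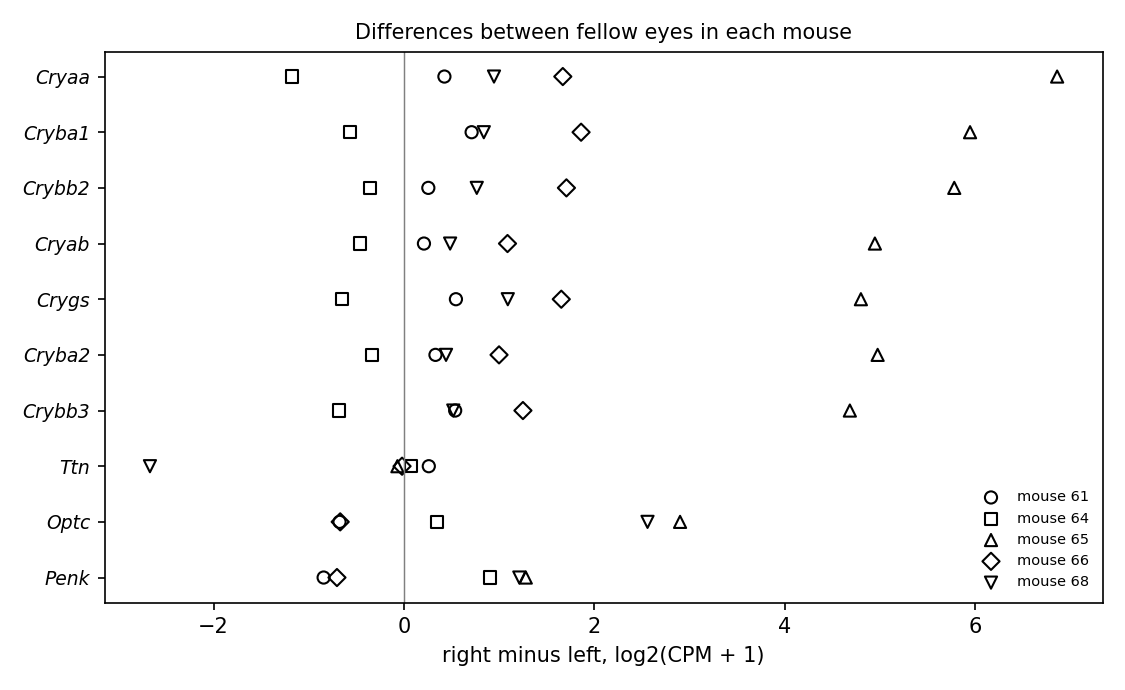
Right-minus-left difference in log2(CPM + 1) of 10 genes that passed the between-eye test, with a symbol for each of 5 mice. Crystallin genes reach 4.69 to 6.86 in mouse 65, Ttn −2.67 in mouse 68, and Optc and Penk are above 0 in mice 64, 65 and 68 and below 0 in mice 61 and 66.

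Mice differed from each other far more clearly than sides did. Limma's moderated F-test called 81 genes (1964 at an unadjusted p under 0.05), 17 of them on the X or Y chromosome and 64 on neither. Xist, the RNA that silences an X chromosome, was at 706.5 to 801.8 CPM in both retinas of mice 61 and 65 and at 0.78 to 1.87 CPM in mice 64, 66 and 68. The Y-linked genes Kdm5d, Uty, Eif2s3y and Ddx3y were at 22.9 to 38.7 CPM in those 3 mice and at most 0.0967 CPM in mice 61 and 65. Both retinas of every number thus matched in sex-linked genes.

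Among other genes the widest difference was that of Egr1, at 32.4 and 26.1 CPM in the left and right retina of mouse 61 and at 1.27 to 3.58 CPM in the other 8 (range of mouse means 3.52 log2 units, adjusted p = 3.76e-06). Fos (18.2 and 15.2 CPM in mouse 61, 3.80 to 6.27 CPM in the others, adjusted p = 0.00018) and Nr4a1 (12.9 and 11.3 against 5.04 to 7.32 CPM, adjusted p = 0.0016) were likewise highest in both eyes of mouse 61. Of 18 tested immediate early genes 4 passed over all genes, the fourth being Ier2 (named after its values were seen), and 9 passed adjusted over the list alone. The peptide transporter gene Slc15a2 ranged over 1.44 log2 units, from 12.5 and 14.5 CPM in mouse 64 to 32.6 and 45.0 CPM in mouse 65. Pisd-ps1, Selenbp1, Cdcp3, Hba-a2, Map3k14 and Ccn4 ranged over 0.94 (Ccn4) to 1.19 (Pisd-ps1) log2 units. Pisd-ps1 is a pseudogene and Hba-a2 has a near-identical copy, so the values of both are uncertain. Of the 64 genes, 32 lay farthest from the median of the mice in mouse 61, and 23 genes were called in all without that mouse, against 39 without mouse 68, 53 without mouse 66 and 41 without mice 65 and 68.

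Over all tested genes the mouse took a median 56.1% of the sum of squares, where exchangeable libraries would give 43.6%. The side took 3.3%, where they would give 5.9%. Without mouse 61 the share of the mouse was 45.4%, and without any other single mouse 55.4% to 56.3%. Much of the excess over exchangeable libraries thus rested on mouse 61. Both libraries of that mouse also stood at an end of library makeup. In the left and right retina they had the highest sums of CPM over listed genes (346696 and 334460). Their mitochondrial share of that sum was the lowest (1.08% and 1.21%), and that of small RNA genes the highest (13.2% and 12.1%). Whether the animal or the library makeup set mouse 61 apart was not tested. Right-minus-left profiles of different mice did not run the same way. Across genes, 5 of the 10 pairs of mice correlated negatively, from −0.444 for mice 64 and 66 to 0.402 for mice 65 and 66.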

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

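All tests of explanations in this part were chosen after the result was seen, and the threshold of the lens test was reset once: it was written for 11 genes but first run on the 4 that passed the filter, of which 3 were highest in the right retina of mouse 65, a count it read against lens tissue. It was then rewritten as a share and run on all 11 in the table. The muscle test was first made on the tested genes, 7 of 8 of them highest in the left retina of mouse 68, which the filter and the pattern itself had favoured, and was replaced by the genes under the filter. A library was picked out when it stood apart from the other 4 of its side by more than Dixon's 95% critical value of 0.71. Of 254 groups of 5 libraries looked at (library measures, list means and named genes), 35 passed. Chance gives about 13 (1 in 20), but many of the genes were named for large differences between eyes or mice and move together, so that an excess was built in.

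The right retina of mouse 65 stood apart most often, in lens genes above all. It was highest in Cryaa (387 CPM, others at most 42 CPM), Cryba1 (170 CPM), Crybb2 (120 CPM), Cryab (111 CPM), Crygs (56.2 CPM), Cryba2 (46.7 CPM), Crybb3 (40.5 CPM), Arhgef5 (2.72 CPM) and Olfml3 (4.34 CPM), in the mean of the matrix list (3.2 against 2.9 to 2.96 log2 units) and in that of the Müller glia list (4.96 against 4.84 to 4.87). The left retina of mouse 68 was highest in Ttn (190 CPM, others at most 27.4 CPM), Myh4 (21.8 CPM), Atp2a1 (13.6 CPM), Acta1 (10 CPM) and the mean of the muscle list (4.08 against 1.54 to 1.59), and lowest in Gfap (2.32 CPM). Its fellow right retina was highest on its side in Myh4 (1.19 CPM, others at most 0.501).

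Tissue from outside the retina is a candidate explanation for these shifts of lens, matrix, fibroblast and muscle genes. If lens tissue came with the right retina of mouse 65, lens genes other than crystallins should peak there too, and 8 of the 11 in the table did (10% each by chance), 5 of the 7 under the filter among them, with Mip at 23.9 CPM, while Lenep, Hsf4 and Birc7 peaked elsewhere, as did 4 of the 13 tested crystallins (Crygb, Crygc, Crygd and Cryge, highest in the right retina of mouse 66), which lens tissue in mouse 65 leaves unexplained. Skeletal muscle in the left retina of mouse 68 would raise muscle genes together, and of the 19 list genes under the filter, which took no part in the pattern, 14 peaked there, with Ckm at 4.66 CPM and Tnnt3 at 4.18 CPM. In the 4 mice other than 68 the muscle list differed by −0.008 on average (SD 0.083), so the −2.33 of mouse 68 was not shared at its size. A smaller shared muscle difference stays open, since mouse 68 was picked for its large difference. Acta1, Myh4 and Atp2a1 were also at most 0.65 CPM in the other left retinas, where log2(CPM + 1) understates change. For the other lists a shared difference stays open too. Of these, 0 of 6 kept most of their mean difference without mice 65 and 68, but these mice were picked for their large differences. No biological explanation was tested because the lens side is unknown.

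Both retinas of mouse 61 stood apart in activity genes: Egr1 (32.4 CPM left, 26.1 CPM right), Fos (18.2 and 15.2 CPM) and Nr4a1 (12.9 and 11.3 CPM). Its left retina was also highest in Opn1sw (128 CPM), Rps21 (5.95 CPM) and the mean of the dopamine list (3.64), and its right retina was highest in Map3k14 (8.87 CPM) and in the share taken by the 10 most abundant genes (18.6%). The right retina of mouse 64, whose raw files were unequal, was highest in Penk (11 CPM) and lowest in the mean of the cone list (4.45 against 4.62 to 4.67). The left retina of mouse 66 had the largest denominator of its side (1 CPM for 108 counts, 0.00925 CPM per count) and the highest Atf4 (69.4 CPM), and the right retina of mouse 66 the highest mean of the heat shock list (4.41 against 4.29 to 4.31).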

How the results depend on the processing

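The fit without mice 65 and 68, limma-voom and the length and GC correction were chosen after seeing the data; the cause of the changes below was not tested except where fewer genes or mice were used. The planned edgeR test was not run, as whole reads could not be recovered. Limma called 0 genes between right and left in all 20 settings, with 172 to 856 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0669 (without mouse 64). Leaving out each mouse gave 5 to 14 lists, 23 to 54 between-eye genes and 23 to 88 genes between mice. The share of the mouse was then 45.4% (without mouse 61) to 56.3%, and 2 to 4 always-named genes passed the threshold over that list. With a mean of at least 5 CPM, 7 lists, 19 between-eye genes and 1 always-named gene (Egr1; Vip is under that filter) passed. Without mice 65 and 68, 3 lists, 4 between-eye genes and 41 genes between mice passed. An estimated correlation and fry each left 0 lists, a robust prior gave 109 or, per gene, 0 between-eye genes, and eBayes without trend 36 genes between mice. With no replicate block, and with the mouse as a random block, 0 genes, 9 lists and 1 always-named gene (Vip) passed; the immediate early, heat shock and synaptic lists lost their call in both. Every other count was within 1.5 times the reported one. The mitochondrially encoded list had adjusted p from 3.79e-07 to 0.591 leaving out each mouse, turning lower on the right without mouse 64, when the cytosolic ribosomal list (0.045 to 0.839) turned higher and passed. The pigment epithelium list turned lower without mice 65 and 68 (0.945). Of 1441 values of 78 named genes under alternatives, none passed and 30 changed sign, in 19 genes. What depth limits was not tested, since the counts behind 1 CPM come from an inferred step.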

Other observations

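A test of mouse against mouse also called retinal genes that the naming rule did not pick. Nr2e3, a transcription factor of rods, was at 105 to 132 CPM in both retinas of mice 61 and 65 and at 160.4 to 210.5 CPM in mice 64, 66 and 68 (adjusted p = 0.0043), the same division of the mice as that of Xist and the Y-linked genes. Sgk1, a kinase induced by glucocorticoids, was at 93.1 to 99.6 CPM in mouse 64 and at 59.0 to 65.5 CPM in mouse 68 (adjusted p = 0.0079), and Usp2, a deubiquitinase of the circadian system, at 34.1 to 38.0 CPM in mice 64 and 68 and at 23.0 to 28.7 CPM in the rest (adjusted p = 0.0029). These 3 genes were named after their values were seen. None of the genes of the circadian list passed.

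Of the 48 between-eye genes, 10, Penk included, shared the signs of Penk (right higher in mice 64, 65 and 68, lower in mice 61 and 66), while 15 had mouse 64 opposite to the other 4 mice and 9 had mice 65 and 66 opposite to the rest. Of all tested genes 2.97% had the signs of Penk, where chance gives 3.12%. Among them were Optc, Fbln1, Vcan, Ltbp2, Ogn, Fbn1, Col18a1, Sned1 and Penk itself, chosen after their values were seen. Fbln1 differed by 2.12 and 2.07 log2 units in mice 65 and 68 and by −0.54 and −0.75 in mice 61 and 66. Vcan differed by 1.77 and 1.62 against −0.20 and −0.59. The labels name no condition with this pattern.

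Of the tests below, those of length and GC content and of other groupings of lists and of always-named genes were set before their result was seen, and the rest after. For the genes between right and left, the real count of 0 is reached by any split, 100 of 100 here (10 libraries into 5 and 5, the real one included), which says nothing about chance, and the highest other gave 1442. For the gene lists, 14 of 100 splits gave 12 or more, with a highest other of 14, so chance is not excluded. Most of the 100 splits part only 1 or 3 pairs, so with the mouse as a block they rest on fewer mice than the real one. Some also repeat the same fit, so the share of 100 is only a rough guide. Among the 16 splits that part all pairs of fellow eyes, as the real one does, 4 gave 12 or more lists, with a highest other of 15, and 5 gave 1 or more genes. The split with 1442 genes is one of these 16. It sets apart, in 5 of 5 pairs, the eye with the lower mean of mitochondrially encoded genes, which in 5 of 5 pairs is also the eye with the higher mean of cytosolic ribosomal protein genes. In every pair the same eye also had the higher sum of CPM over listed genes. The sums were 346696 against 334460 in mouse 61, 332076 against 322042 in mouse 64 and 331746 against 325431 in mouse 65. In mice 66 and 68 they were 327419 against 321661 and 329573 against 324914. The split thus runs along a difference in library makeup, whose cause was not tested and has no name in the labels. It is not read here as the lens.

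Right-minus-left profiles had opposite signs between some mice, and those of mice 64 and 66 correlated at −0.444 across genes. A trend of each library with gene length or GC content is argued against as the whole cause, since the correlation was −0.404 after that correction. Lens and muscle genes are argued against as well, since it was −0.433 without them. The mice divided much as in the split with 1442 genes. It set apart the left eye in mice 61, 64 and 68 and the right eye in mice 65 and 66. Profiles of mice 61, 64 and 68 correlated positively with each other (0.316, 0.088 and 0.177), as did those of mice 65 and 66 (0.402). Between these groups correlations ran from −0.444 to −0.117, but mice 65 and 68 correlated at 0.106. Whether the profiles stay opposed without that division was not tested. A difference in handling, and a response to the lens, stay open and were not tested, as the labels give neither.

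The lower Egr1 and Vip on the right of 5 of 5 mice concerns genes long tied to visually guided eye growth, and its call rests on a list of 13 genes. As the lens side is unknown, the pattern has no measured link to eye growth here. Without mice 65 and 68 the differences were −0.36 (SE 0.083) and −0.41 (SE 0.108), and the weaker moderated t was −3.74. The differences thus did not rest on these 2 mice alone. Whether carried-over tissue had a part in them cannot be decided by that fit. The pattern was picked for being present in 5 of 5 mice, so its sign in the mice left was fixed beforehand. Those mice may not be free of such tissue, as the lens list differed by 0.30, −0.56 and 1.19 in mice 61, 64 and 66. For the same reason of choice, the fit adds no support for the pattern itself. The length and GC correction left 96.2% or more of both differences, still in 5 of 5 mice. A difference in time or handling between the first and the second eye taken could lower activity genes on the right, but it cannot be told apart from an effect of side, because the labels give neither the order nor the lens. That 13 of the 17 other tested immediate early genes were lower there restates the list result, whose call is lost with an estimated correlation (adjusted p = 0.43) and without the mouse as a block (0.255). Of the 16 splits that part all pairs, 2 gave 2 or more always-named genes past the threshold, the real one with 2 and another with 5, and 16 splits are too few to give a share under 0.05.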
